A study of Mus musculus with 11 samples.

How the data were processed

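Total RNA was measured on Affymetrix gene-level arrays in 11 samples of adult C57Bl/6 mouse stomach. Whole stomach came from 4 groups that cross tamoxifen with rapamycin: vehicle (sunflower oil, 2 arrays), tamoxifen (2 arrays), rapamycin (3 arrays) and rapamycin plus tamoxifen (2 arrays). The remaining 2 arrays held isolated parietal cells and the stomach cells left after parietal cells were taken out. Per the labels, tamoxifen was given at 5 mg per 20 g mouse for 3 days and rapamycin at 0.6 mg per 20 g mouse for 10 days, as daily injections into the peritoneum. The labels call the whole-stomach samples biological replicates; whether each array is 1 mouse is not given in the sources used here. RNA was purified on RNeasy columns, checked on a Bioanalyzer, amplified with the RiboAmp HS kit and labelled with biotin (Enzo).

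The authors deposited a table of log2 expression values made with RMA in Partek, whose versions and background, summarization and normalization settings are not given in the sources used here. Per probe set, the table gave 41345 values for each array. Medians of the 9 whole-stomach arrays lay between 4.95 and 5.09. The parietal-cell and remaining-cell arrays had medians of 3.67 and 3.68, so the fractions look normalized apart from the whole stomachs, and they were compared only with each other. The number of arrays limits the precision, and signal over background is not given in the sources used here.

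The platform's probe table paired 25335 probe sets with a gene, of which 23521 named 1 symbol and 1814 named several, while 16010 were not listed with a gene. By gene ID, 23328 probe sets were matched to the RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols changed. No genome build was named for the array, so no coordinates are given. Keeping for each gene the probe set of highest mean over the 9 whole-stomach arrays gave 22180 genes, with no filter on dim probe sets. Control probe sets could not be identified in the table.

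Gene changes were fitted with limma 3.58.1 in R 4.3.3 on the log2 values, with 1 mean per whole-stomach group and 1 shared spread (5 residual degrees of freedom, prior 3.86). Contrasts were tamoxifen against vehicle, rapamycin against vehicle, the combination against vehicle, against rapamycin and against tamoxifen, the interaction, and each drug averaged over the other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Simulated data had the same shape and spread per gene, with noise independent between genes and arrays. Deviations shared between arrays or genes, which the real data show, were not simulated. In the simulation 42.5% of genes changed by 1 log2 unit and 94.5% of genes changed by 2 were recovered for tamoxifen against vehicle. For the combination against rapamycin, the shares were 56.5% and 98%, and for tamoxifen averaged over rapamycin 80% and 98.5%. Errors after ± are limma standard errors of the log2 change.

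Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over 33 lists within a contrast, and again with the correlation estimated from the data. The 34 lists held 396 entries, of which 360 were measured, 2 through a synonym. They covered gastric cell types (parietal, chief, neck mucous and metaplasia, pit mucous, endocrine) and cell states (cell cycle, immediate early genes, p53 targets, autophagy and lysosome, sterol synthesis, ATF4 and amino acids, glycolysis, ribosome biogenesis, protein folding, respiratory chain, NRF2 targets, xenobiotic metabolism, interferon response, inflammatory cytokines, oestrogen response). Other cell types and tissues were macrophages, neutrophils, T cells, B cells, mast cells, MHC class II, smooth muscle, fibroblasts, endothelium, forestomach squamous epithelium, exocrine pancreas, intestine, adipose and blood. The blood list had only 1 measured gene and was not tested. Counts of members called are given over all genes and adjusted over the list alone.

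The fraction arrays had no replicates and no test. Genes at least 2 log2 units higher, or lower, in the parietal-cell fraction formed gene sets that camera tested on the whole-stomach arrays. List medians between fractions were set against 10000 random lists of like expression. The contrasts, lists, sets and alternatives, and the rule for which genes are named, were fixed before the data were examined. The rule took, per contrast, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, or the 10 genes of smallest p where fewer than 10 were called. From each list it took up to 4 called members of largest change, or 2 members where none was called. For the fractions it took the 12 largest differences each way among genes above the median.

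Alternatives were quantile normalization again, median centring, a filter on dim probe sets, the mean of a gene's probe sets, every probe set by itself, only the groups compared, limma with a trend and robust prior, array weights, a replicate block, each whole-stomach array left out in turn, other set thresholds and the estimated correlation. Squamous signal as a covariate, vehicle 2 and tamoxifen 2 left out together, and a replicate block with crossed numbers were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.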

Results

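Expression of 22180 genes was measured on 9 whole-stomach arrays and on 2 arrays of separated stomach cells. Tamoxifen, a drug that binds oestrogen receptors, was crossed with rapamycin, an inhibitor of the growth kinase mTORC1. The groups were vehicle (n = 2), tamoxifen (n = 2), rapamycin (n = 3) and rapamycin plus tamoxifen (n = 2), with 1 array each for isolated parietal cells and for the other stomach cells. Keratin and cornified-envelope genes of the squamous forestomach differed between arrays within groups. The mean of 11 such genes was 5.13 and 4.78 in the vehicle arrays, 9.38 and 4.95 in the tamoxifen arrays, 9.41, 8.21 and 5.33 in the rapamycin arrays, and 8.73 and 8.95 in the combined arrays. Vehicle 2 and tamoxifen 2 were closer to each other (Pearson r across genes 0.988) than vehicle 2 was to vehicle 1 (0.981) or tamoxifen 2 to tamoxifen 1 (0.971).

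**Figure D1:**
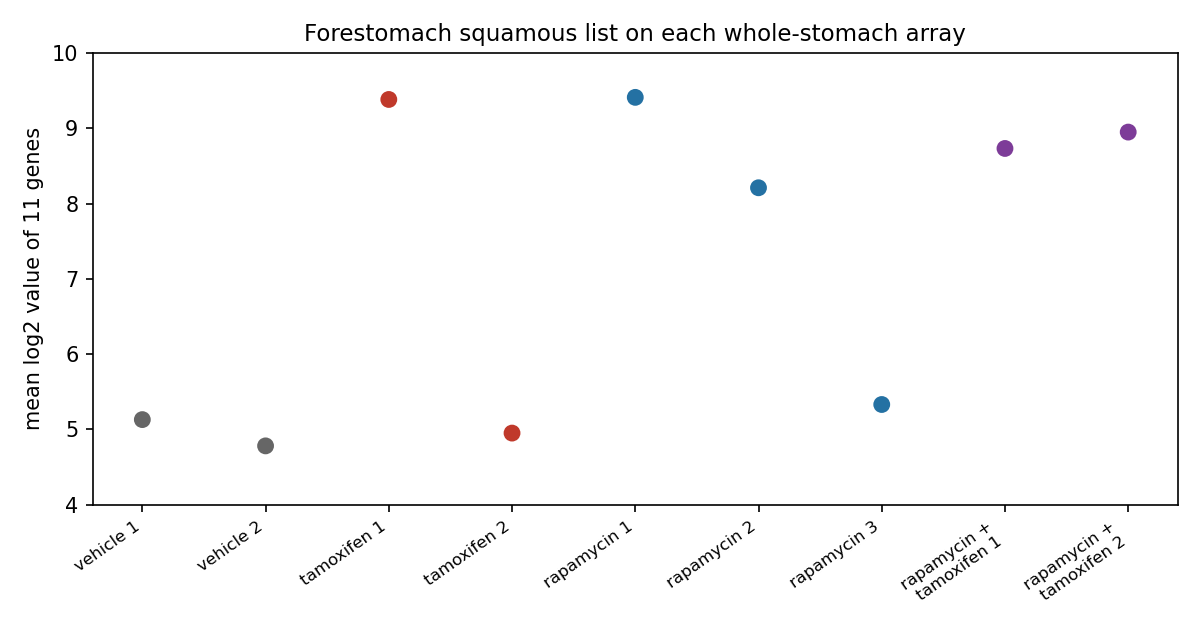
Mean log2 expression of 11 forestomach squamous genes on each of the 9 whole-stomach arrays, 1 point per array, coloured by group. Both vehicle arrays, tamoxifen 2 and rapamycin 3 sat between 4.78 and 5.33, and the other 5 arrays between 8.21 and 9.41.

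The separated cells show which transcripts were richer in isolated parietal cells than in the other cells. Parietal-cell markers stood higher in the parietal fraction by a median of 3.30 log2 units, and 12 of the 14 list members exceeded a difference of 2. The largest differences included the fatty acid transporter Cd36 (6.59), the iron hormone gene Hamp (6.59) and its relative Hamp2 (5.61). Among them too were the ribonuclease gene Rnase1 (6.30) and the anion exchanger Slc26a9 (5.84). Others were the apolipoprotein gene Apoa4 (5.65), the glycosyltransferase gene B4galnt2 (5.49) and the monocarboxylate transporter Slc16a7 (5.34). 2210409E12Rik (7.27), Rasgrp3 (6.01), Fabp1 (5.93) and Rab30 (5.46) stood higher too. In the other direction stood Ifitm2 (-7.56) and the mast cell protease genes Mcpt2 (-7.48) and Mcpt1 (-7.27). Endocrine genes stood lower as well: the hormone genes Gast (-6.46) and Ghrl (-5.74), the serotonin enzyme gene Tph1 (-5.97), and the granin gene Chgb (-5.95). Lower immune genes were Lilrb4a (-7.15), Ccl3 (-7.01), Gzmb (-5.80) and Il6 (-5.75). Pla2g10os also stood lower (-6.74).

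By list, mast cell (median -4.80), endocrine (-3.25), pit mucous (-2.77) and neck mucous (-1.47) genes were lower in the parietal fraction, as were cell cycle (-1.02) and sterol synthesis (-1.05) genes. Respiratory chain genes were higher by a median of 1.03, above 99.98% of random lists, and all 14 of them were positive. Chief cell genes had a median of -0.66 and squamous genes of -0.14. With 1 array per fraction no test was possible. In all, 289 genes were at least 2 log2 units higher in the parietal fraction and 455 at least 2 lower. The values correlated across genes with r = 0.914.

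Tamoxifen against vehicle asks what tamoxifen alone does to the stomach. Genes of the parietal cell fell: the anion exchanger Slc26a7 by -2.75 ± 0.22 (adjusted p = 0.00205) and the potassium channel Kcnj16 by -2.18 ± 0.17 (adjusted p = 0.00205). All 14 parietal list members were lower on average, 2 of them called over all genes and 11 adjusted over the list alone (median -0.76, camera adjusted p = 5.81e-13; adjusted p = 0.18 with an estimated correlation). The median was -0.47 without tamoxifen 1. The proton pump subunits that acidify the stomach lumen stood at -0.69 for Atp4a (adjusted p = 0.198) and -0.82 for Atp4b (adjusted p = 0.142). Neither passed over all genes, and both were named after their values were seen. Egf, a growth factor gene, fell by -3.01 ± 0.21 (adjusted p = 0.00173). Of the 12 genes named above as highest in the parietal fraction, 7 fell: B4galnt2 (-3.56), Rnase1 (-3.26), Hamp2 (-2.92), Apoa4 (-2.78), Cd36 (-1.73), Rasgrp3 (-1.62) and Slc16a7 (-1.55).

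Among the 289 genes of the parietal fraction, 75 fell and 0 rose with tamoxifen, with 2423 of all genes at an unadjusted p under 0.05 in limma. Their median was -0.54 (camera p = 6.10e-45; p = 0.0106 with an estimated correlation). The median was -0.67 between tamoxifen 1 and vehicle 1 and -0.46 between tamoxifen 2 and vehicle 2. The 455 genes low in the parietal fraction had a median of 0.13, with 27 higher and 13 lower (camera p = 5.23e-05; p = 0.235 with an estimated correlation). That shift was lost without vehicle 1 (0.036) or without tamoxifen 2 (0.0085).

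Digestive enzyme genes of the chief cell, the zymogen-secreting cell of the gland base, fell with tamoxifen. Pga5, a pepsinogen gene, fell by -3.64 ± 0.38 and the chitinase gene Chia1 by -2.10 ± 0.19. The intrinsic factor gene Cblif fell by -1.60 ± 0.13 and Bhlha15, a regulator of secretory-cell structure, by -1.21 ± 0.20. Of 10 chief cell genes, 4 fell and 1 rose over all genes and adjusted over the list alone (median -0.25, camera adjusted p = 2.93e-05; adjusted p = 0.17 with an estimated correlation). The median was -0.50 without vehicle 2 and -0.47 without tamoxifen 1. In the neck mucous and metaplasia list, Muc6, the gland mucin gene, fell by -1.92 ± 0.34. There, 3 genes were higher and 2 lower adjusted over the list alone, and the list itself did not pass (median 0.43, camera adjusted p = 0.0501). It passed for the combination against rapamycin (0.52, camera adjusted p = 0.00485) and against vehicle (0.37, camera adjusted p = 0.0375), though in neither with an estimated correlation. With 1 array left out, these medians ran from 0.21 to 0.62 and from 0.18 to 0.44. With 1 array left out in turn Bhlha15 kept its call in 2 of 9 cases and Muc6 in 3.

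Proliferation genes rose together. Of 24 cell cycle genes, 20 rose over all genes and 23 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 1.58e-38; adjusted p = 0.00723 with an estimated correlation). Rrm2, which makes deoxyribonucleotides, rose by 1.55 ± 0.16 and Birc5 by 1.30 ± 0.14. The topoisomerase gene Top2a rose by 1.29 ± 0.19 and the mitotic kinase gene Cdk1 by 1.26 ± 0.14. The list median was 0.93 between the arrays numbered 1, which differ in squamous signal (9.38 against 5.13), and 1.16 between those numbered 2, which are alike in it (4.95 against 4.78). Of 16 ribosome biogenesis genes, 5 rose and 15 did so adjusted over the list alone (median 0.66, camera adjusted p = 1.41e-16; adjusted p = 0.0531 with an estimated correlation). Among them were the nucleolar genes Dkc1 (1.06), Nop58 (1.04), Nop56 (0.99) and Npm1 (0.87), whose calls held in 1, 2, 4 and 1 of 9 cases with 1 array left out in turn.

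Some stress and immune genes also moved. The stress transcription factor gene Atf3 rose by 1.09 ± 0.21 and Ier3 by 0.95 ± 0.15. They belong to an immediate early list of 11 (2 called, 5 adjusted over the list alone, median 0.71, camera adjusted p = 4.50e-07; adjusted p = 0.18 with an estimated correlation). The list median was 0.34 without vehicle 2 and 0.38 without tamoxifen 2, and with 1 array left out in turn Atf3 kept its call in 1 of 9 cases and Ier3 in 3. Oas2, an interferon-induced antiviral gene, rose by 1.99 ± 0.35. In its list, 8 of 9 interferon genes passed adjusted over the list alone (median 1.43, camera adjusted p = 1.33e-08; adjusted p = 0.18 with an estimated correlation). The median was 0.65 between the arrays numbered 1 and 1.68 between those numbered 2, and 0.61 without tamoxifen 2; Oas2 kept its call in 2 of 9 cases. Mast cell genes fell as a list (median -1.14, camera adjusted p = 6.44e-10, adjusted p = 0.17 with an estimated correlation). Of 8 members 2 were called, 7 adjusted over the list alone: Mcpt1 at -2.92 ± 0.43 and the receptor gene Kit at -1.34 ± 0.20. Kit did not follow Mcpt1 throughout: in the combination against rapamycin Kit fell, while Mcpt1 stood higher. Macrophage genes had a median of 0.58, with lysozyme gene Lyz2 at 1.33 ± 0.27 (1 of 12 called, 4 adjusted over the list alone, camera adjusted p = 5.53e-08; adjusted p = 0.22 with an estimated correlation). Without tamoxifen 2 the macrophage median was 0.29, and Lyz2 kept its call in 1 of 9 cases. Fibroblast genes had a median of 0.50 (0 of 11 called by limma, 4 adjusted over the list alone, camera adjusted p = 2.48e-06; adjusted p = 0.23 with an estimated correlation), which was 0.25 without vehicle 1 and 0.26 without tamoxifen 2.

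Metabolic lists shifted by less. Sterol synthesis genes had a median of 0.45, with Pmvk, a mevalonate pathway kinase, at 1.27 ± 0.15 (1 of 15 called, 1 adjusted over the list alone, camera adjusted p = 2.02e-07; adjusted p = 0.23 with an estimated correlation). With 1 array left out the sterol median ran from 0.31 to 0.84. It was 0.84 without vehicle 2, 0.79 without tamoxifen 1 and 0.34 without tamoxifen 2. NRF2 targets had a median of 0.32, with the antioxidant gene Srxn1 at 0.89 ± 0.16 (1 of 9 called, 4 adjusted over the list alone, camera adjusted p = 1.12e-04; adjusted p = 0.23 with an estimated correlation). The NRF2 median was 0.19 without vehicle 1, 0.20 without tamoxifen 2, 0.49 without vehicle 2 and 0.54 without tamoxifen 1, and Srxn1 kept its call in 1 of 9 cases. In the autophagy and lysosome list Gabarapl1 fell (-0.97) and the protease gene Ctsl rose (0.78), for a median of -0.16 (camera adjusted p = 0.0246; adjusted p = 0.23 with an estimated correlation). Its call was lost without vehicle 1, vehicle 2 or tamoxifen 1, with an adjusted p of up to 0.236; Gabarapl1 kept its call in 1 of 9 cases and Ctsl in 0. Respiratory chain genes had a median of -0.14 (camera adjusted p = 0.0203; adjusted p = 0.53 with an estimated correlation). That call was lost without vehicle 2 or tamoxifen 1, with an adjusted p of up to 0.673, and the median was -0.01 without tamoxifen 1 and -0.33 without tamoxifen 2. Squamous genes had a median of 1.99 (1 of 11 called, 1 adjusted over the list alone, camera adjusted p = 1.24e-04; adjusted p = 0.38 with an estimated correlation). Sprr1a rose by 1.77 ± 0.31. The list median was -0.15 without tamoxifen 1 and 4.51 without tamoxifen 2.

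Other named genes rose with tamoxifen: Cyp2b10, a cytochrome P450 of drug metabolism, by 2.68 ± 0.43 (adjusted p = 0.0216), Kcne3, a potassium channel subunit, by 2.26, and Vnn1 by 2.24. S100g, a calcium-binding protein gene, rose by 2.19, Hspa1b, a heat shock gene, by 2.19, and the guanylate cyclase activator gene Guca2b by 2.15. Smaller rises were D17H6S56E-5 by 2.02, Khdc1a by 1.93, the acute phase gene Saa3 by 1.83, Mir1949 by 1.83 and the keratin gene Krt7 by 1.78. Falls included Gm12888 (-3.97 ± 0.21, adjusted p = 4.02e-04), Gm5409 (-3.46), the trypsin gene Try4 (-3.36), Gpr155 (-3.03), Necab1 (-2.81) and Mug1 (-2.79). In all, limma called 381 genes, 207 higher and 174 lower, and 226 of them changed more than 2-fold. That balance was not stable: quantile normalization gave 180 higher and 209 lower, and falls outnumbered rises without any single array except tamoxifen 1. None had overlapping groups; among all genes 27.3% did not overlap, against 33.3% by chance. Leaving out any 1 of the 9 arrays gave between 95 genes (without vehicle 1) and 213 (without tamoxifen 1). It gave 153 without vehicle 2, 180 without tamoxifen 2, 202, 186 and 187 without rapamycin 1, 2 and 3, and 190 without either combined array. Of 51 named genes, 20 were called each time, among them Gm12888, Egf, Slc26a7, Kcnj16, Pga5, Cblif, Rrm2 and Cdk1. The 4 arrays fitted alone called 0 in limma, with 1318 at an unadjusted p under 0.05, and with the squamous mean as a covariate limma called 164.

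**Figure D2:**
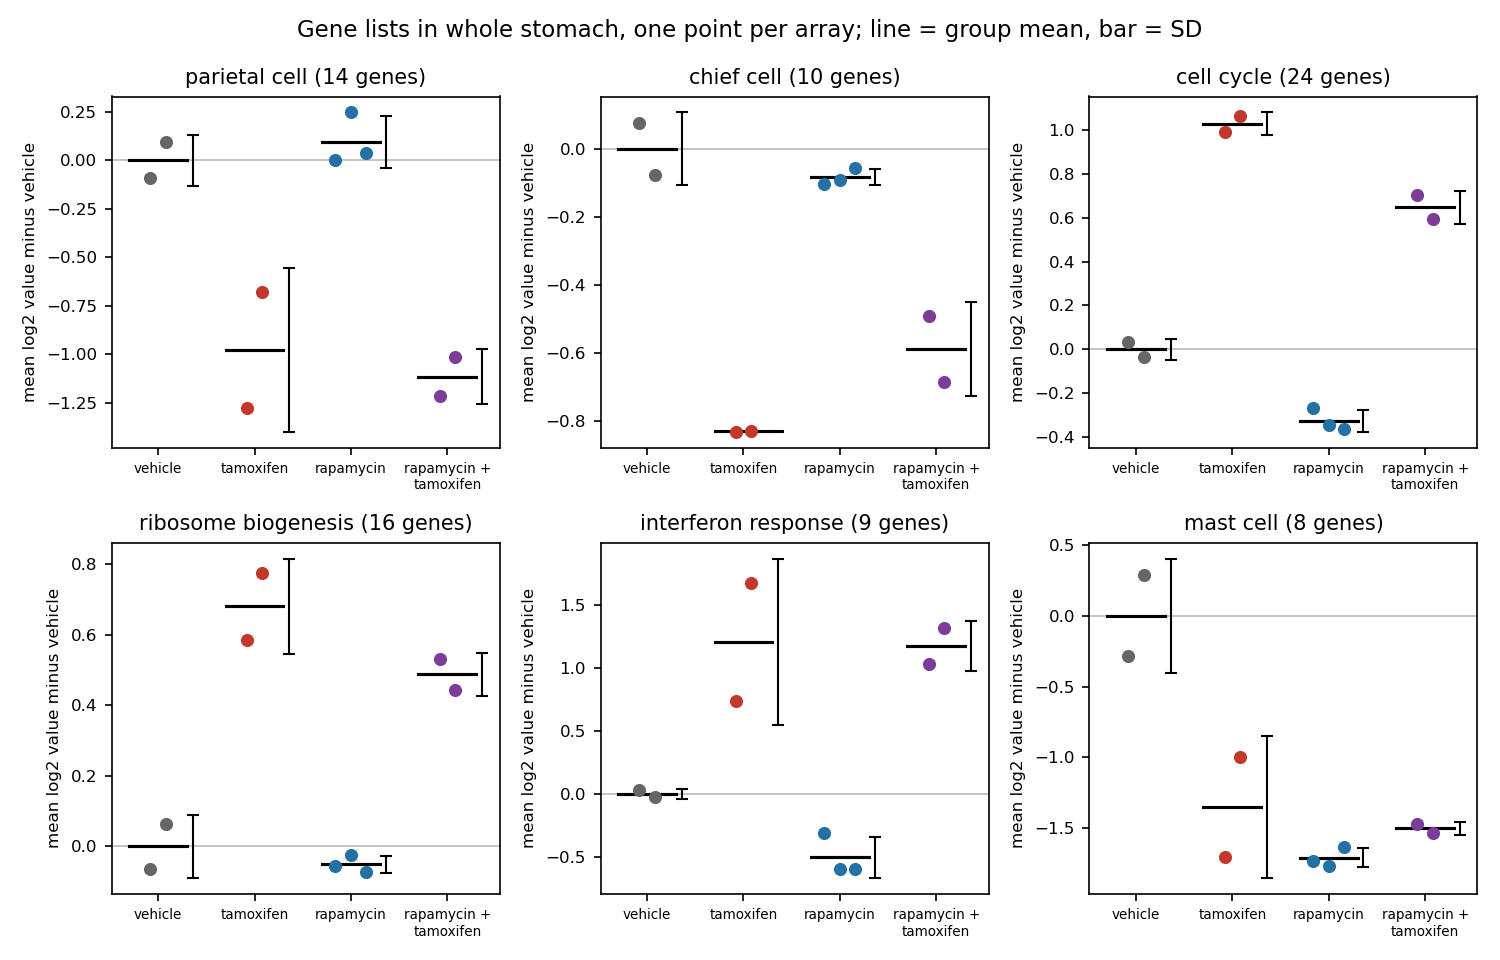
Mean log2 value of 6 gene lists minus the vehicle mean (vertical) on each whole-stomach array, by group (horizontal), with group means as lines and SDs as bars. Cell cycle genes stood higher and parietal cell genes lower on every tamoxifen and combined array, and mast cell genes stood lower on every treated array.

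Rapamycin against vehicle asks what rapamycin alone does. The activity of mTORC1 was not measured. Mast cell protease genes fell: Mcpt1 by -4.46 ± 0.39 (adjusted p = 0.00758), Mcpt2 by -3.57 ± 0.41 and the tryptase gene Tpsb2 by -1.37 ± 0.14. Of the list, 3 of 8 mast cell genes were called and 6 adjusted over the list alone (median -1.33, camera adjusted p = 3.83e-09; adjusted p = 0.20 with an estimated correlation). The pseudogene Mcpt-ps1 fell by -1.58 ± 0.17. Atp6v0d2, a proton ATPase subunit gene, fell by -4.63 ± 0.30 (adjusted p = 0.00132), with the phospholipase gene Pla2g4c (-3.46), the sialyltransferase gene St3gal4 (-2.73), Lypd8 (-1.25) and the cytokine receptor gene Il31ra (-1.07). Chst4, a sulfotransferase gene, rose by 2.21 ± 0.21 and the clock gene Per1 by 1.26 ± 0.15.

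Cell cycle genes shifted down without a single call over all genes in limma (10 of 24 adjusted over the list alone, median -0.35, camera adjusted p = 1.14e-06; adjusted p = 0.20 with an estimated correlation). Mki67 stood at -1.10 and Top2a at -0.84. Adipose genes stood higher by a median of 0.86 (5 of 6 adjusted over the list alone, camera adjusted p = 4.15e-06; adjusted p = 0.315 with an estimated correlation), with Retn at 2.65 and Adipoq at 2.54. Smooth muscle genes stood higher by 0.27 (2 of 10 adjusted over the list alone, camera adjusted p = 9.21e-06; adjusted p = 0.20 with an estimated correlation). Squamous genes had a median of 2.40 (adjusted p = 0.66 with an estimated correlation), which was 1.54 without rapamycin 1 and 3.65 without rapamycin 3. It was -0.07 with the squamous covariate, which is the mean of these same genes and so removes their mean change by construction. Limma called 11 genes, 2 higher and 9 lower, with 1977 at an unadjusted p under 0.05. Without vehicle 2 it called 3, without rapamycin 1, 2 or 3 it called 4, 7 and 6, without either combined array 6, and without either tamoxifen array 20. Atp6v0d2, Pla2g4c and St3gal4 were called each time.

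The combination against vehicle gave falls in parietal genes again. Kcnj16 fell by -2.50 ± 0.17, Slc26a7 by -2.37 ± 0.22, the chloride-bicarbonate exchanger gene Slc4a2 by -1.30 ± 0.25 and Trim50 by -1.09 ± 0.19 (4 of 14 called, 11 adjusted over the list alone, median -1.0, camera adjusted p = 1.58e-12; adjusted p = 0.26 with an estimated correlation). Pga5 (-2.87), Chia1 (-1.75) and Cblif (-1.16) fell among chief cell genes, while Tnfrsf19 rose (0.91). Cell cycle genes rose, 7 of 24 over all genes and 19 adjusted over the list alone (median 0.65, camera adjusted p = 5.42e-20; adjusted p = 0.0341 with an estimated correlation). Largest were the replication helicase genes Mcm6 (1.08), Mcm4 (1.05) and Mcm7 (0.93). Gast, the gastrin gene, rose by 2.96 ± 0.55 (adjusted p = 0.0467), Chgb by 1.73 and Cyp2b10 by 2.66. Irf7, an interferon regulator gene, rose by 2.08 and Oasl2 by 2.02. Also higher were Ifi205 by 2.14, Ddx60 by 1.75, Myc by 1.61, Kcne3 by 1.99, Hspa1b by 1.88, D17H6S56E-5 by 1.95 and Snora75 by 1.81.

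Mast cell genes fell in the combined group too (median -1.36, camera adjusted p = 2.60e-08, adjusted p = 0.26 with an estimated correlation). Of 8 members 3 were called, 7 adjusted over the list alone: Mcpt1 at -3.30, Mcpt2 at -2.48 and Kit at -1.50. Against rapamycin Kit fell as well, while Mcpt1 stood higher. Further falls were Gm12888 (-4.83), B4galnt2 (-4.26), Gpr155 (-3.53), Gm5409 (-3.29), Try4 (-3.05), the lipase gene Lpl (-2.98), Egf (-2.84), Rnase1 (-2.81), Apoa4 (-2.79) and 2210409E12Rik (-2.71). Squamous genes were higher on both combined arrays than on either vehicle array (median 3.75; adjusted p = 0.36 with an estimated correlation), and the epithelial gene Slurp1 rose by 2.67. Limma called 254 genes, 91 higher and 163 lower, none with overlapping groups. Without combined array 1 or 2 the count was 17 and 28, without vehicle 1 or 2 it was 75 and 114. Without rapamycin 1, 2 or 3 it was 129, 111 and 119, and with the squamous covariate it was 10. Of 46 named genes, 7 were called each time and 6 with the covariate; Gast and Cyp2b10 kept their calls in 3 of 9 cases.

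The combination against rapamycin asks whether tamoxifen acts when rapamycin is given. Parietal genes fell, with Slc26a7 at -2.96 ± 0.20 (adjusted p = 6.89e-04), Kcnj16 at -2.49 ± 0.16, the histamine receptor gene Hrh2 at -1.52 ± 0.25, Slc4a2 at -1.31 ± 0.22 and Atp4b, again named after its value was seen, at -0.99 (adjusted p = 0.046). Of the 14 list members 7 fell, and 12 did so adjusted over the list alone (median -1.05, camera adjusted p = 2.08e-15; adjusted p = 0.18 with an estimated correlation). Among the 289 parietal-fraction genes 123 fell and 0 rose, at a median of -0.69 (camera p = 2.49e-59; p = 0.00588 with an estimated correlation), with 3085 of all genes at an unadjusted p under 0.05 in limma. Chief cell genes Pga5 (-2.07), Chia1 (-1.32) and Cblif (-1.04) fell as well.

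Cell cycle genes rose under rapamycin, 19 of 24 over all genes and 24 adjusted over the list alone (median 1.04, camera adjusted p = 3.04e-34; adjusted p = 0.00960 with an estimated correlation). Top2a stood at 1.49 ± 0.18, Birc5 at 1.46 ± 0.13, Ccnb2 at 1.23 ± 0.17 and Bub1 at 1.19 ± 0.24. Ribosome biogenesis genes rose by a median of 0.49 (3 of 16 called, 12 adjusted over the list alone, camera adjusted p = 1.46e-11; adjusted p = 0.0799 with an estimated correlation). Interferon genes rose by a median of 2.03 (5 of 9 called, 8 adjusted over the list alone, camera adjusted p = 8.34e-11; adjusted p = 0.14 with an estimated correlation): Irf7 by 3.07 ± 0.30, Ifit1 by 2.84 ± 0.53, Oas2 by 2.58 ± 0.32 and Usp18 by 2.18 ± 0.45. Outside the list stood Ifit1bl1 (3.51), Oasl2 (3.06), Ddx60 (3.01), Oas1g (2.87) and Rtp4 (2.60). Smooth muscle genes fell, Actg2 by -0.93 ± 0.13 and Des by -0.91 ± 0.17 (2 of 10 called, 8 adjusted over the list alone, median -0.42, camera adjusted p = 8.88e-08, adjusted p = 0.0659 with an estimated correlation). Endothelium (-0.53, camera adjusted p = 1.93e-05) and adipose genes (-0.61, camera adjusted p = 0.0214) stood lower too, though not with an estimated correlation. Here 16 lists passed at the preset correlation, 7 higher and 9 lower.

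Other rises were Atp6v0d2 (3.61 ± 0.30), the cystine transporter gene Slc7a11 (2.34) and the milk-clotting protease gene Cym (1.96). Further falls were Gm12888 (-4.41), B4galnt2 (-4.07), Rnase1 (-3.87), Gpr155 (-3.72), Hamp2 (-3.69), Prnd (-3.25) and Gm5409 (-3.05), followed by Try4 (-2.80), Egf (-2.79), Mug1 (-2.70), the desaturase gene Scd1 (-2.70 ± 0.46) and Kit (-1.76). Limma called 543 genes, 251 higher and 292 lower, none with overlapping groups. There, 39.1% of all genes did not overlap, against 20% by chance. Without combined array 1 or 2 the count was 39 and 71, without rapamycin 1, 2 or 3 it was 262, 153 and 214. Of 46 named genes, 13 were called each time and 44 with the squamous covariate. These 5 arrays fitted alone called 1102.

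Most genes called for tamoxifen without rapamycin changed in the same direction with it. Of the 381 genes called without rapamycin, 372 had the same sign with it (97.6%, exact binomial 95% interval 95.6% to 98.9%, genes not being independent), against 65.8% of all genes. In both contrasts 118 genes rose, against 2.34 expected by chance, and 135 fell, against 2.29, with 0 called in opposite directions. These contrasts share no array, but they share 1 estimate of the spread per gene. The expected counts leave that out and so may be too low. Across all genes the changes correlated with Pearson r = 0.663 and Spearman rho = 0.486. The median ratio among the 381, with rapamycin over without, was 0.855. Those genes were chosen by their calls without rapamycin, which favours large values there. A ratio below 1 can come from that choice, so it does not show a weaker response under rapamycin. Mcpt1, called without rapamycin, was an exception, at -2.92 without it and 1.17 with it. Atp6v0d2 (-0.07 and 3.61) and Scd1 (0.96 and -2.70), called only with it, differed too; these were chosen after their values were seen.

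**Figure D3:**
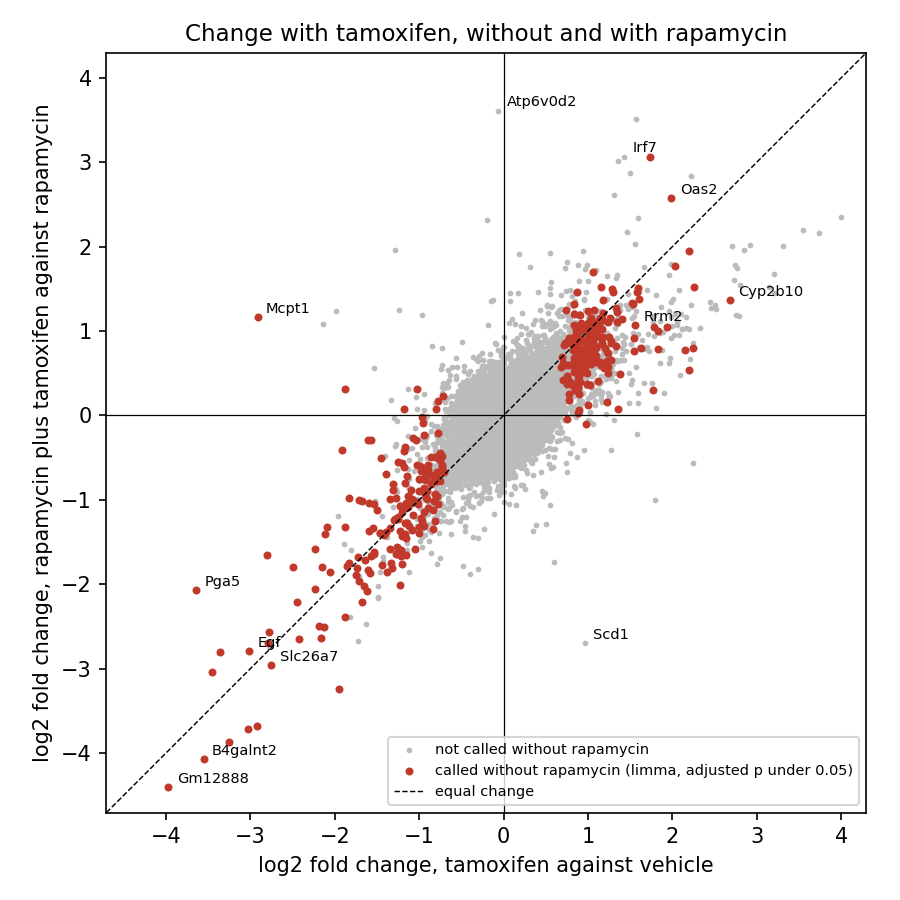
Log2 fold change of each gene with tamoxifen against vehicle (horizontal) and with the combination against rapamycin (vertical), 1 point per gene, red where called without rapamycin. Of the 381 red points 372 have the same sign on both axes, and Mcpt1, Atp6v0d2 and Scd1 lie away from the line of equal change.

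The combination against tamoxifen asks what rapamycin adds to tamoxifen. Sterol synthesis genes shifted down by a median of -0.74 (12 of 15 adjusted over the list alone, camera adjusted p = 8.83e-13; adjusted p = 0.26 with an estimated correlation). Lss, the lanosterol synthase gene, stood at -1.40 and Insig1, a sterol sensor gene, at -1.21 ± 0.19. Cell cycle genes shifted down by -0.39 (10 of 24 adjusted over the list alone, camera adjusted p = 2.01e-10; adjusted p = 0.15 with an estimated correlation). ATF4 and amino acid genes shifted by -0.38 (adjusted p = 0.205 with an estimated correlation) and glycolysis genes by -0.33 (adjusted p = 0.26 with an estimated correlation). Fibroblast genes (-0.46; adjusted p = 0.497 with an estimated correlation) and smooth muscle genes (-0.26; adjusted p = 0.205 with an estimated correlation) passed at the preset correlation as well. The fibroblast median was -0.21 without tamoxifen 2 and -0.70 without tamoxifen 1, the smooth muscle median -0.14 without combined array 2, and the glycolysis median -0.50 without tamoxifen 1. Macrophage genes had a median of -0.47 (camera adjusted p = 0.00122; adjusted p = 0.52 with an estimated correlation), which was lost without tamoxifen 2 (-0.13, adjusted p = 0.368).

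In this contrast 14 of 33 lists passed camera at the preset correlation, 3 higher and 11 lower, and 0 with an estimated correlation. Chief cell genes stood higher by 0.25 (adjusted p = 0.403 with an estimated correlation), which was lost without combined array 1 and was 0.08 without tamoxifen 2. Endocrine genes stood higher by 0.12 (adjusted p = 0.520 with an estimated correlation), lost without tamoxifen 2 (0.11) and 0.22 without tamoxifen 1. NRF2 targets (-0.33; adjusted p = 0.497 with an estimated correlation), protein folding (-0.35; adjusted p = 0.622 with an estimated correlation), respiratory chain (-0.21; adjusted p = 0.622 with an estimated correlation) and ribosome biogenesis genes (-0.21; adjusted p = 0.497 with an estimated correlation) stood lower. Without tamoxifen 2 all 4 lost their calls (-0.27, -0.10, -0.06 and -0.07), and without tamoxifen 1 they stood at -0.43, -0.57, -0.37 and -0.33. The respiratory chain call was also lost without combined array 1 and the ribosome biogenesis call without combined array 2.

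No single gene passed in limma, where 1257 had an unadjusted p under 0.05 and the smallest adjusted p was 0.423. The 10 genes of smallest p were the kallikrein genes Klk1 (1.72) and Klk1b5 (1.28), the metabolic kinase gene Pdk4 (1.02), G630018N14Rik (2.20), Insig1 (-1.21), Sectm1b (1.10), Guca2b (-1.34), Gast (3.16), the innate receptor gene Tlr1 (-0.95) and A830082N09Rik (0.98). Squamous genes had a median of 1.57 (adjusted p = 0.76 with an estimated correlation) that turned to -0.61 without tamoxifen 2 and whose call was lost without vehicle 1, vehicle 2 or combined array 2. Leaving out rapamycin 1 or tamoxifen 2 gave 1 gene each.

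The interaction asks whether the tamoxifen change differs under rapamycin. No gene passed in limma, with 627 at an unadjusted p under 0.05 and a smallest adjusted p of 0.223. Smooth muscle genes differed as a list, by a median of -0.58 (6 of 10 adjusted over the list alone, camera adjusted p = 2.56e-13; adjusted p = 0.0326 with an estimated correlation), with Actg2 at -1.01 ± 0.20 and Des at -0.91 ± 0.25. Mast cell genes differed by 1.27 (6 of 8 adjusted over the list alone, camera adjusted p = 1.12e-11, adjusted p = 0.20 with an estimated correlation). Relative to vehicle, the mast cell list mean was -1.35 with tamoxifen, -1.71 with rapamycin and -1.50 with both. The falls with each drug thus did not add, which by itself gives a positive interaction. The genes of smallest p were St3gal4 (2.19), Atp6v0d2 (3.68), Mcpt1 (4.08), Pla2g4c (2.49), Tpsb2 (1.33), the tubulin gene Tubb6 (-1.36), Scd1 (-3.66), Cym (3.24), Mcpt2 (3.23) and Gm6498 (1.34), none of which passed.

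Averaged over rapamycin, tamoxifen lowered 11 of 14 parietal genes (12 adjusted over the list alone, median -0.88, camera adjusted p = 6.42e-15; adjusted p = 0.21 with an estimated correlation). It raised 23 of 24 cell cycle genes (24 adjusted over the list alone, median 1.02, camera adjusted p = 1.50e-36; adjusted p = 0.00821 with an estimated correlation). Ribosome biogenesis genes rose in 11 of 16 cases (16 adjusted over the list alone, median 0.64, camera adjusted p = 1.15e-15; adjusted p = 0.0602 with an estimated correlation). Interferon genes rose in 7 of 9 (9 adjusted over the list alone, median 1.79, camera adjusted p = 9.79e-11; adjusted p = 0.194 with an estimated correlation). Averaged over tamoxifen, rapamycin shifted sterol synthesis genes by -0.59 (12 of 15 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation). It shifted cell cycle genes by -0.41 (14 of 24 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). Limma called 1298 genes for tamoxifen, 719 higher and 579 lower, and 11 for rapamycin, 7 higher and 4 lower. Without combined array 1 or 2, or without rapamycin 2, the tamoxifen count was 613, 658 and 785. The rapamycin count was 68 without tamoxifen 1, 17 without vehicle 1, 6 without rapamycin 2, 4 without tamoxifen 2, 3 without vehicle 2 or rapamycin 1, and 2 without rapamycin 3 or combined array 1. It was 0 without combined array 2, where 1625 had an unadjusted p under 0.05.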

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

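The treatment, resemblance, high-level and equal-loss tests in this part were chosen only after the result was seen; the further squamous genes, the slope with vehicle level and the slope with enrichment were set down before. Squamous forestomach genes stood high on 5 whole-stomach arrays and low on 4, in a way that crossed the groups. A different share of forestomach tissue on each array fits the values: 16 further squamous genes followed the list over the 9 arrays with a median r of 0.984. Rapamycin was excluded as the whole cause, because rapamycin 3 stood below tamoxifen 1, the highest array without rapamycin (-4.05 log2 units). Tamoxifen was excluded as the whole cause, because tamoxifen 2 stood below rapamycin 1, the highest array without tamoxifen (-4.46). Each of these highest arrays had received the other drug, and both vehicle arrays stood low. A variable rise with either drug was therefore not excluded. The further squamous genes cannot tell a larger forestomach share from a joint rise of such genes. How much forestomach each sample held is not given in the sources used here.

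Vehicle 2 and tamoxifen 2 resembled each other more than their group partners. Forestomach share was excluded as the whole cause, because their deviations still correlated at 0.532 across 8945 genes unrelated to the squamous list. Handling shared by replicate number across all groups was excluded, since the lowest correlation of same-numbered arrays was -0.112, between tamoxifen and the combination; handling shared only by vehicle and tamoxifen, whose same-numbered arrays correlated at 0.561, was not. Of the 60 ways to split the arrays within rapamycin strata, only the real tamoxifen labels called as many as 1298 genes. With 60 splits this is the smallest share that can be reached. The next highest split set vehicle 2, tamoxifen 2 and both combined arrays against the rest and gave 1278. It keeps the real combination against rapamycin, which called 543 genes by itself. The count therefore does not set the vehicle and tamoxifen labels apart from that split, and chance was not excluded for them. Handling shared by vehicle and tamoxifen, an unlabelled batch or an animal difference stays open, and forestomach share was not excluded. No biological explanation was tested. For rapamycin 1 of 60 splits, the real one, called as many as 11 genes, against 1 for the next.

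Genes of the parietal fraction fell unequally with tamoxifen, by a median of -0.17 in the lowest expression band and -1.02 between levels 10 and 12. Genes with higher vehicle levels fell more (Spearman rho -0.495 across genes, permutation p = 0.0001, the smallest the permutations can give). Up to a level of 12 the falls thus did not shrink as compression of high signals would make them. Genes of low level have little room to fall, however, and that alone can give such a slope. Above a level of 12 the median of -0.759 came from 2 genes (-0.823 and -0.695), too few to decide. Compression at that level was not excluded. The slope predicted for expression outside parietal cells was seen: the more enriched a gene, the further it fell (rho -0.372, permutation p = 0.0001). Level was not held fixed in this test. Genes of low level have little room to show either enrichment or a fall, so this slope cannot decide the question. The spread among 21 strongly enriched genes was 3.51 times their median standard error, so their falls differed by more than the variation between arrays. That standard error leaves out differences between probe sets in background and response. An equal loss of parietal-cell RNA, the biological explanation the design gives, was therefore not excluded as the only cause.

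The tamoxifen change differed under rapamycin, by camera's test of the interaction, for 16 lists: parietal cell (-0.203), chief cell (0.155), immediate early (-0.308), sterol synthesis (-0.536), ATF4 and amino acid (-0.256), glycolysis (-0.251), ribosome biogenesis (-0.158), protein folding (-0.124), macrophage (-0.466), mast cell (1.266), interferon response (0.487), smooth muscle (-0.58), fibroblast (-0.401), endothelium (-0.322), squamous (-1.022) and adipose (-0.73). Only smooth muscle kept its call with an estimated correlation. With 1 array left out in turn, mast cell and smooth muscle were called in all 9 cases, and sterol synthesis (-0.73 to -0.13), ATF4 and amino acid (-0.33 to -0.18) and macrophage (-0.78 to -0.13) in 8. Adipose (-1.01 to -0.39), glycolysis (-0.41 to -0.11) and fibroblast (-0.68 to -0.11) were called in 7, and chief cell (0.06 to 0.35), immediate early (-0.53 to -0.07) and endothelium (-0.47 to -0.16) in 6. Parietal cell (-0.39 to 0.018) and protein folding (-0.38 to 0.015) were called in 5, interferon response (-0.16 to 1.22) and ribosome biogenesis (-0.31 to -0.02) in 4, and squamous (-3.17 to 1.30) in 3. Among probe sets outside the genes analysed, those listed with several genes gave 16 calls of 1814 for tamoxifen against vehicle. They gave 23 for the combination against rapamycin, and those listed with no gene gave 12 and 54 of 16010. The 16 include amylase probe sets and several Rnu1b1 probe sets with the same value (1.95), so they are not all separate genes.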

How the results depend on the processing

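The squamous covariate, the pair of vehicle 2 and tamoxifen 2 left out, and the crossed replicate block were chosen only after the result was seen; a term for these 2 arrays was also tried and dropped, because it groups arrays by their measured values. Counts of genes called are given in the order of the settings, and the cause was not tested unless fewer arrays or genes show it. With dim probe sets left out, limma called 603 genes for tamoxifen against vehicle, 815 for the combination against rapamycin and 37 for averaged rapamycin, with fewer genes tested. With only the groups compared, it called 0 (1318 at an unadjusted p under 0.05), 7 for rapamycin and 1102 for the combination against rapamycin; this setting cannot give a value for the interaction or the averages. A trend and robust prior gave 35 for averaged rapamycin. Array weights gave 20 for tamoxifen, 6 for rapamycin, 1834 for the combination against rapamycin, 4 for averaged rapamycin and a same-direction share of 100%. Under the replicate block, limma called 170 for tamoxifen, 149 for the combination against vehicle, 260 for the combination against rapamycin, 1 for the interaction and 0 for averaged rapamycin (3113 at an unadjusted p under 0.05); 158 of the 170 and 242 of the 260 were called before, the labels share only a number, and same-numbered deviations correlated between -0.112 and 0.561. The crossed replicate block called 0 in limma for the combination against tamoxifen (1549 at an unadjusted p under 0.05).

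The squamous covariate gave 164 (155 called before), 4, 10 and 3 genes for tamoxifen, rapamycin, the combination against vehicle and averaged rapamycin. It turned the adipose list for the combination against vehicle to -0.046. The squamous list then stood at -0.37 with tamoxifen, -0.073 with rapamycin and 0.21 for the interaction. Since the covariate is the mean of these same squamous genes, their mean change is removed by construction. Without vehicle 2 and tamoxifen 2 together, which leaves 1 vehicle and 1 tamoxifen array so that all spread comes from the rapamycin and combined arrays, the counts were 105 for tamoxifen, 1 for rapamycin, 1102 for the combination against rapamycin, 2 against tamoxifen and 2 for averaged rapamycin, the squamous list against tamoxifen turned to -0.61 and the immediate early list for the interaction to 0.053. The set of genes low in the parietal fraction had a median of 0.062 (camera p = 0.0888) at a threshold of 3 log2 units and 0.13 (p = 0.235) with an estimated correlation. With an estimated correlation, lists called went from 14 to 1 for tamoxifen, 12 to 0 for rapamycin, 16 to 1 for the combination against vehicle and against rapamycin, 14 to 0 against tamoxifen and 16 to 1 for the interaction, by camera.

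Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 95 to 213 genes for tamoxifen, 3 to 20 for rapamycin, 17 to 376, 39 to 643 and 0 to 1 for the combination against vehicle, rapamycin and tamoxifen, 0 to 0 for the interaction, 613 to 1452 for averaged tamoxifen and 0 to 68 for averaged rapamycin; fewer arrays account for part of this. The parietal-fraction set ranged from -0.69 to -0.48 with tamoxifen and -0.73 to -0.63 under rapamycin, the low set from 0.0085 to 0.25, and the same-direction share from 96.3% to 98.6%. The squamous list ranged from -3.17 to 1.30 for the interaction and from -0.61 to 3.97 for the combination against tamoxifen, turned without tamoxifen 1 and without tamoxifen 2. For the interaction the parietal list ranged from -0.39 to 0.018 and the protein folding list from -0.38 to 0.015, both turned without tamoxifen 2, and the interferon list from -0.16 (without tamoxifen 1) to 1.22. With dim probe sets left out, the B and plasma cell list for rapamycin against vehicle was 0.21. Quantile normalization, median centring and the mean of probe sets kept tamoxifen between 283 and 389 genes and the combination against rapamycin between 420 and 659; of 174 gene results by contrast, 20 of which had no call, 8, 25 and 9 lost their call, in the same order. More lost it with the replicate block (53), array weights (56), the squamous covariate (65), only the groups compared (67 of 164) and vehicle 2 and tamoxifen 2 left out (52). With 1 array left out, the number that lost it ran from 17 (without tamoxifen 1) to 92 (without combined array 1). Quantile normalization turned the balance of rises and falls to 180 and 209 for tamoxifen and 6 and 10 for averaged rapamycin, only the groups compared turned it to 215 and 123 for the combination against vehicle and 568 and 534 against rapamycin, and leaving out tamoxifen 2 turned it to 589 and 610 for averaged tamoxifen. A covariate for the 3′ to 5′ signal of Actb and Gapdh was not run, since no control probe sets could be identified, and a pseudocount does not apply to log2 values.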

Other observations

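A few single genes named for other digestive tissues were called with tamoxifen on whole-stomach arrays. The lipase gene Cel fell by -1.72 ± 0.35 (limma adjusted p = 0.0492) and the colipase gene Clps by -0.82 ± 0.13 (limma adjusted p = 0.0214), and under rapamycin by -1.96 and -1.02; both stood lower in the parietal fraction, Clps by -2.95. Only these 2 of 7 exocrine pancreas genes were called, also adjusted over the list alone, and the list did not pass (median -0.12, camera adjusted p = 0.0578). Outside that list, the trypsin gene Try4 (-3.36) and Gm5409 (-3.46) were called lower with tamoxifen too. So were a probe set shared by Try10 and Gm5409 (-4.09, limma adjusted p = 0.00916) and probe sets shared by several amylase genes (-2.21 to -2.07, limma adjusted p = 0.0357 to 0.0386). With 1 array left out in turn Cel kept its tamoxifen call in 1 of 9 cases and Clps in 3, and neither kept it with the squamous covariate. The endocrine gene Chgb rose by 1.52 ± 0.21 with tamoxifen and by 1.33 under rapamycin, while its list did not pass with tamoxifen (median -0.20, camera adjusted p = 0.311). On single arrays Gast stood at 9.73 and 9.08 with the combination, 8.30, 6.28 and 6.71 with rapamycin, 6.48 and 6.00 with tamoxifen, and 6.46 and 6.42 with vehicle.

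The cytochrome gene Cyp2c55 rose in the combination against vehicle by 1.66 ± 0.26 (limma adjusted p = 0.0228), and Psat1, of serine synthesis, rose by 1.16 ± 0.20 with tamoxifen (limma adjusted p = 0.0297). With 1 array left out in turn these calls held in 3 and 1 of 9 cases, and neither held with the squamous covariate. The xenobiotic list (median 0.13, camera adjusted p = 0.164) and the ATF4 and amino acid list (0.09, 0.0578) did not pass with tamoxifen. Other lists that did not pass were pit mucous (median 0.02, mean -9.85e-04, 0.872), p53 targets (0.02, 0.507), glycolysis (0.10, 0.780), protein folding (-0.02, 0.538), inflammatory cytokines (0.11, 0.338), neutrophil (0.33, 0.256), T cell (-0.04, 0.507), B and plasma cell (-0.06, 0.256), MHC class II (-0.08, 0.715), smooth muscle (0.11, 0.173), endothelium (-0.14, 0.202), intestine (0.01, 0.538), adipose (0.26, 0.507) and oestrogen response (0.23, 0.140).

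For rapamycin against vehicle, further lists passed camera at the preset correlation, each lost without at least 2 single arrays. They were endocrine (0.40), sterol synthesis (-0.41), respiratory chain (-0.14), NRF2 (-0.18), xenobiotic (0.27), B and plasma cell (-0.28) and interferon (-0.55). The first 4 lost their calls without vehicle 2, at 0.10, -0.03, -0.03 and -0.16, and the last 3 without vehicle 1. All but sterol synthesis lost them without rapamycin 2, and some without rapamycin 1, rapamycin 3 or a combined array. Without vehicle 1, sterol synthesis stood at -0.71, respiratory chain at -0.24 and NRF2 at -0.36, and without rapamycin 2 the B and plasma cell list stood at -0.18. With an estimated correlation none passed: adjusted p = 0.659, 0.755, 0.83, 0.659, 0.315, 0.315 and 0.755, in that order. Principal component 1 held 40.2% of the variance of the whole-stomach arrays and component 2 held 28.7%.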
